A study of Mus musculus with 9 samples.

How the data were processed

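Gene expression was measured on 9 oligonucleotide microarrays, each hybridised with RNA from sorted mouse back skin cells. The mice were CD1 females with 2 fluorescent reporters, one red under Lef1 control and one a green histone fusion under keratin 14 control, so that dermal papilla and epithelial cells could be separated by flow cytometry. The labels give 3 populations: bulge (green, CD34 positive, P-cadherin low), hair germ (green, CD34 negative, P-cadherin high) and dermal papilla (red, not green, depleted of cells with CD45, CD117 or integrin alpha 7, and per the sample titles also of CD34). Each population was collected on postnatal days 43, 56 and 69, called early, middle and late telogen, with 1 array per population and day. Per the labels the RNA went through 2 rounds of amplification. Whether the 3 populations of a day came from the same mice is not stated.

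The authors deposited MAS5 probe set signals, which are intensity values on a linear scale, made with GCOS. The versions, the scaling target and the probe sets used for scaling are not stated, and the 2% trimmed mean ran from 165 to 207 between arrays. All 22690 probe sets had a value in all 9 arrays. Detection calls were not used here. Array data give no count depth, so the number of arrays limits the precision.

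From there, 64 control probe sets were set aside for quality measures, and log2(signal + 16) was taken with no further scaling between arrays. A probe set was kept if it lay above its own array's median in at least 3 of the 9 arrays, which left 12801. Probe sets were named from the annotation supplied with the series, where 20393 pointed to a single gene, 691 to several and 1555 to none, and 20364 symbols were matched to the current gene table. A gene was represented by its brightest kept probe set, giving 7796 genes tested of 12394 named on the array. No genome coordinates were used.

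Tests used R 4.3.3 and limma 3.58.1. A linear model with population and age as additive terms was fitted to all 9 arrays (4 residual degrees of freedom), with eBayes and a mean-variance trend. Two-sided p values were adjusted by the Benjamini-Hochberg method and called below 0.05. The contrasts were dermal papilla minus the mean of hair germ and bulge, hair germ minus bulge, day 69 minus day 43 and day 56 minus day 43. The 3 ages served as replicates of a population, so the spread behind each p value includes age effects that differ between populations. Age was kept as a term because it is a factor of the design. The correlation of same-age deviations between populations ran from -0.097 to 0.184 across genes, and that of different ages from -0.261 to 0.243. Every same-age value that involved bulge was positive, from 0.03 to 0.112. These values do not settle whether the arrays of a day were paired.

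Within a population, 2 arrays were compared with no test. A gene was counted when it differed at least 2-fold on the log2(signal + 16) scale and the higher array was above its own median. Gene lists fixed before the data were examined, 16 of cell type markers and 22 of pathways or processes, were tested in each contrast with camera at a preset correlation of 0.01 where at least 3 members were measured, which held for 34 of the 38 lists. Camera was also run with an estimated correlation, and fry was run as an alternative. Within a population, a list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes the arrays and is not a test.

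Genes were named by a rule set before the data were examined. For each tested contrast these were the 10 largest differences in each direction among genes past the threshold with the same sign at every age or in every population, or the 5 smallest p values where fewer than 5 genes passed. For each population these were the 8 largest differences in each direction between days 69 and 43. For each list these were up to 4 members that passed or reached 2-fold, or up to 2 where none did. Members of the signal lists that reached 2-fold in dermal papilla could also be named. Genes of the sort gates served only as a label check.

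The steps were tested on simulated data made from the fitted spread, with 200 genes changed out of 7796. For the dermal papilla contrast, 45.5% of genes changed by a log2 of 1 and 91.5% of those changed by 2 were recovered. For hair germ against bulge the shares were 0% and 87.5%, and for day 69 against day 43 they were 0% and 86.5%. These shares depend on the number of genes changed. In the data 1541 genes passed for hair germ against bulge and 1062 of them were at least 2-fold apart, so smaller differences could pass there. Camera with the preset correlation gave p below 0.05 for 10 of 100 random lists of 20 genes in the hair germ and bulge contrast and for 20 of 20 lists raised by a log2 of 1. In hair germ, 0 of 60 random lists fell outside the central 95% of matched lists, and 60 of 60 raised lists lay above it.

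Alternatives planned before the data were examined were pseudocounts of 1 and 64, quantile normalization, centring each array on its median, no filter, a stricter filter, the mean of a gene's probe sets, eBayes with no trend, a fold minimum, each array left out, no age term, only hair germ and bulge arrays, and day 56 in place of day 69. Added after the data were seen were the fit with the day 43 dermal papilla and day 69 hair germ arrays left out, the fit with the 3 arrays whose GAPDH 3'/5' ratio exceeded 6 left out and no age term (which keeps 1 hair germ array, so that the other populations supply the spread), and day 69 against day 56.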

Results

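The series asked how dermal papilla, hair germ and bulge differ, and how each changes as the second resting phase (telogen) of the mouse hair cycle runs toward regrowth. It held 9 arrays, 3 per population and 3 per age. Median probe set signals ran from 39.9 to 56.3. Arrays of a population resembled each other most: Pearson's r across genes was 0.965 to 0.985 between bulge arrays, 0.938 to 0.956 between dermal papilla arrays and 0.920 to 0.934 between hair germ arrays. Between populations r was 0.825 to 0.883 for bulge and hair germ, 0.608 to 0.654 for bulge and dermal papilla, and 0.572 to 0.656 for dermal papilla and hair germ. Genes are not independent replicates. The first 2 principal components, 65.4% and 18.8% of the variance, set dermal papilla apart from epithelium and hair germ apart from bulge.

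Of the sort genes, Cd34, Krt14 and Lef1 followed the labels. Cd34 was at 11.69 ± 0.08 (SD, n = 3) log2 units in bulge, 4.70 ± 0.89 in hair germ and 5.36 ± 0.32 in dermal papilla. Krt14, whose promoter drives the green reporter, was at 10.91 ± 0.29, 13.02 ± 0.38 and 5.06 ± 0.69. Lef1 was at 4.23 ± 0.32, 4.99 ± 0.36 and 7.26 ± 1.43, and within dermal papilla it was at 6.09, 6.81 and 8.86 on days 43, 56 and 69. Ptprc (CD45), a depletion marker of the dermal papilla sort, was at 7.17 ± 0.16 in bulge, 5.84 ± 0.42 in hair germ and 4.35 ± 0.27 in dermal papilla. It was lower in hair germ than in bulge by a log2 of -1.33 (limma, adjusted p = 0.00982). The probe set for Cdh3 (P-cadherin) lay above the median of 0 arrays, and those for Kit (CD117) and Itga7 above that of 2 and 1, so they checked nothing. RNA quality differed between arrays. The GAPDH 3'/5' signal ratio was 8.34, 2.97 and 7.90 in hair germ on days 43, 56 and 69, 6.62, 4.13 and 3.78 in dermal papilla, and 4.46, 5.09 and 3.96 in bulge. Actin ratios were 17.7, 3.79 and 16.3 in hair germ, 13.5, 4.32 and 3.12 in dermal papilla, and at most 6.60 in bulge.

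The first comparison addressed which signals the dermal papilla, the mesenchymal cluster at the follicle base, makes toward the epithelium. Compared with the mean of hair germ and bulge, BMP ligands and WNT antagonists were higher as lists in dermal papilla, and keratinocyte markers and mitosis genes were lower (camera with the preset correlation; adjusted p = 0.249 for the first 3 and adjusted p = 0.385 for mitosis genes with an estimated correlation). Crabp1, which encodes a retinoic acid binding protein, was higher by 8.07 ± 0.32 (SE) log2 units, 269-fold (limma, adjusted p = 1.97e-08). It stood at 13.04 ± 0.18 (SD, n = 3) in dermal papilla, 4.74 ± 0.08 in bulge and 5.20 ± 1.02 in hair germ. The WNT antagonist gene Dkk2 was higher by 7.26 and the activin subunit gene Inhba by 7.16. Other large differences were in the matrix genes Spon1 (6.81), Col6a3 (6.71), Pcolce (6.71) and Dpt (6.62), the natriuretic peptide receptor gene Npr2 (6.53), the mesenchymal transcription factor gene Prrx1 (6.38) and the protease gene Fap (6.31). The lowest gene was Krt15, a basal and stem cell keratin, at -7.59 ± 0.58 (SE), followed by Serpinb5 at -7.20. Anchoring and junction genes followed, with Col17a1 at -7.16, Dst at -6.51 and Krt5 at -6.57, together with Clca3a2 (-6.95), Dmkn (-6.86), Ripk4 (-6.77), Pof1b (-6.53) and Scel (-6.52).

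Lists of secreted signals split by family. BMP ligands were higher in 5 of 6 members, also adjusted over the list alone, with Bmp4 at 5.82, Gdf10 at 5.64 and Bmp7 at 2.46 (camera adjusted p = 0.000172, adjusted p = 0.249 with an estimated correlation). WNT antagonists were higher in 6 and lower in 1 of 9, the same counts adjusted over the list alone, including Wif1 (4.33), Frzb (3.09) and Sfrp2 (2.68) beside Dkk2 (camera adjusted p = 0.00338, adjusted p = 0.249 with an estimated correlation). TGF-beta and activin genes were higher in 7 and lower in 3 of 16, or 9 and 3 adjusted over the list alone, with Ltbp1 at 2.89 and Tgfbi at -5.18 (camera adjusted p = 0.0368, adjusted p = 0.416 with an estimated correlation). That call ended under quantile normalization, at adjusted p = 0.0586. BMP response genes were lower in 6 of 10, also adjusted over the list alone, led by Gata3 (-4.68), Id4 (-3.65) and Id2 (-2.95), the Id genes being direct BMP targets (camera adjusted p = 0.0101, adjusted p = 0.463 with an estimated correlation). WNT ligands and R-spondins, which enhance WNT signalling, were not called (camera adjusted p = 0.132). Members Rspo2 (4.98), Rspo1 (4.77) and Wnt5a (3.37) were higher and Wnt4 (-4.50) was lower. FGF ligands were not called either (camera adjusted p = 0.239), although Fgf7, an epithelial mitogen, was higher by 3.93 and Fgf1 was at -1.99. Growth factors outside these families were higher in 9 and lower in 9 of 21, with Mdk at 4.52, Igf1 at 4.10 and Ptn at -5.40. The WNT target genes Notum (6.17) and Nkd2 (4.31) were higher and Lgr5 (-4.01) was lower, in a WNT response list that was not called (camera adjusted p = 0.856), where the median was -0.17, the mean 0.13 and the direction of the test downward.

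Cell identity lists moved with the sort. Dermal papilla markers were higher in 15 and lower in 0 of 16, or 15 and 1 adjusted over the list alone, with Vcan at 6.18 (camera adjusted p = 2.79e-11, adjusted p = 0.249 with an estimated correlation). Dermal fibroblast markers were higher in 8 of 11, also adjusted over the list alone, with Col3a1 at 5.60 and Pdgfra at 5.40 (camera adjusted p = 6.86e-07, adjusted p = 0.249 with an estimated correlation). Keratinocyte markers were lower in 13 of 13, also adjusted over the list alone, including Cdh1 at -6.21 (camera adjusted p = 2.79e-11, adjusted p = 0.249 with an estimated correlation). Epidermal differentiation genes were lower in 6 of 8 (camera adjusted p = 0.00103, adjusted p = 0.385 with an estimated correlation), and bulge stem cell markers were lower in 11 and higher in 2 of 16 (camera adjusted p = 0.00112, adjusted p = 0.249 with an estimated correlation), all the same adjusted over the list alone. Leukocyte markers, of cells that the CD45 depletion of this sort removes, were lower in 4 of 5, also adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.259 with an estimated correlation). Mitosis genes were lower in 27 of 27, also adjusted over the list alone, with the proliferation marker Mki67 at -3.85 (camera adjusted p = 6.98e-10, adjusted p = 0.385 with an estimated correlation). DNA replication genes were lower in 12 and higher in 0 of 21, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.00498, adjusted p = 0.465 with an estimated correlation). Basement membrane and integrin genes were exchanged rather than shifted, with 10 higher, among them Lama2 (6.19) and Nid1 (5.04), and 11 lower, among them Lamb3 (-6.15). Their median was 0.20, their mean -0.29 and camera's adjusted p 0.856.

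In all, 3145 of 7796 genes differed, 1297 higher and 1848 lower in dermal papilla, against 390 expected at an unadjusted p below 0.05, where 3726 were found. Of the 3145, 3121 had the same sign on all 3 days and 1980 were at least 2-fold apart. Camera called 12 of 34 lists with the preset correlation and 0 with an estimated one, while fry, which does not compare a list with other genes, called 25.

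**Figure D1:**
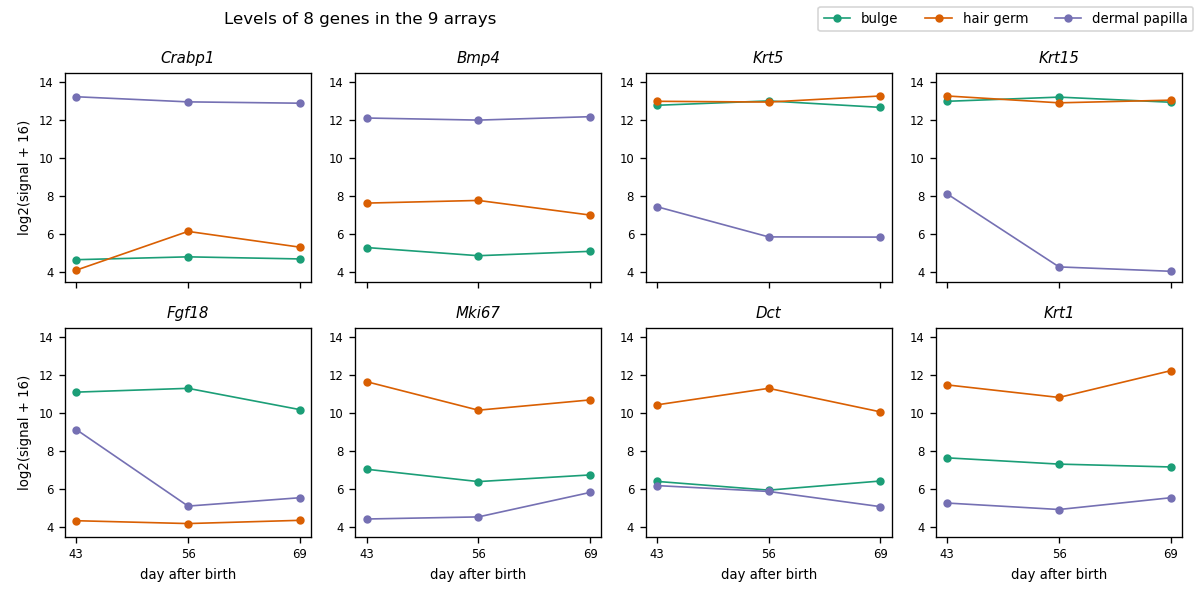
Levels of 8 genes on the 9 arrays, as log2(signal + 16) against day after birth, with 1 point per array and 1 line per population. Crabp1 and Bmp4 were highest in dermal papilla, Fgf18 in bulge, and Mki67, Dct and Krt1 in hair germ, on every day; Krt15 in the dermal papilla array was at 8.13 on day 43 and 4.06 on day 69.

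The second comparison addressed what separates the hair germ, the small epithelial cluster next to the dermal papilla, from the bulge, where stem cells reside. As lists, mitosis, epidermal differentiation and melanocyte genes were higher in hair germ and bulge markers lower (camera with the preset correlation; adjusted p = 0.534 for the first 3 and adjusted p = 0.145 for bulge markers with an estimated correlation). Tcim was higher by 4.43 ± 0.21 (SE) log2 units (limma, adjusted p = 3e-06), at 10.65 ± 0.45 (SD, n = 3) in hair germ and 6.21 ± 0.65 in bulge. The keratin genes Krt6b (4.42 ± 0.97, SE), Krt1 (4.14) and Krt77 (3.87) were also higher, Krt6b with a wide spread of 3.55 (SD) over the 3 hair germ arrays. The call for Krt6b ended without bulge replicate 1 or hair germ replicate 1. The melanin synthesis gene Dct was higher by 4.34, the WNT target Tnfrsf19 by 4.33, Abi3bp by 4.25, Mki67 by 4.11, Phldb2 by 3.99 and the adhesion gene Chl1 by 3.80. After the sort gene Cd34 (-6.99), the lowest was Fgf18, a secreted growth factor gene, at -6.57 ± 0.67 (SE, adjusted p = 0.000107), followed by Sncg (-5.22), the potassium channel gene Kcnk2 (-4.90) and Ppp1r3c (-4.71). Pdlim3 (-4.37), S100a4 (-4.12), Sh3kbp1 (-4.01), Tspan2 (-3.95), the guidance gene Sema3e (-3.94) and the receptor component Ramp1 (-3.86) completed the set.

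Cell division genes showed the broadest difference. Mitosis genes were higher in 27 of 27, also adjusted over the list alone, with Cdc20 at 3.47 and Kif2c at 3.18 (camera adjusted p = 9.52e-22, adjusted p = 0.534 with an estimated correlation). DNA replication genes were higher in 12 of 21, or 14 adjusted over the list alone, led by Uhrf1 (2.31) and Rrm2 (1.95) (camera adjusted p = 0.000251, adjusted p = 0.534 with an estimated correlation). Bulge stem cell markers were lower in 13 of 16, or 14 adjusted over the list alone, with Nfatc1, a regulator of stem cell quiescence, at -2.83 and Ltbp2 at -2.80 (camera adjusted p = 2.27e-12, adjusted p = 0.145 with an estimated correlation). BMP antagonists were lower in 7 of 11, also adjusted over the list alone, with Grem1 at -3.58, Smad6 at -2.18 and Fst at -2.01 (camera adjusted p = 0.000266, adjusted p = 0.534 with an estimated correlation). The BMP targets Id2 (-2.22) and Id3 (-1.73) were lower too, in a BMP response list that was not called (camera adjusted p = 0.298), and the ligands went both ways, with Bmp6 at -3.46 and Bmp4 at 2.38. WNT ligands and R-spondins were higher in 4 of 9, also adjusted over the list alone, namely Wnt16 (2.34), Wnt5a (2.10), Wnt10a (1.32) and Wnt6 (1.30) (camera adjusted p = 0.0207, adjusted p = 0.534 with an estimated correlation). The call for Wnt5a ended with a pseudocount of 64. The feedback target Axin2 was higher by 1.46, in a WNT response list that was not called (camera adjusted p = 0.0891).

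Of the cell type lists other than bulge markers, 2 were called in hair germ against bulge. Epidermal differentiation genes were higher in 5 and lower in 1 of 8, also adjusted over the list alone, with Krtdap at 3.43, Ly6d at 2.80 and Calml3 at -2.81 (camera adjusted p = 0.0128, adjusted p = 0.534 with an estimated correlation). Melanocyte genes were higher in 3 and lower in 1 of 5, or 4 and 1 adjusted over the list alone, with the melanin genes Tyrp1 (3.73) and Pmel (3.16) higher and the regulator Mitf (-2.18) lower (camera adjusted p = 0.0361, adjusted p = 0.534 with an estimated correlation). Cholesterol synthesis genes were higher in 6 of 16, or 7 adjusted over the list alone, led by Cyp51 (2.23) (camera adjusted p = 0.00209, adjusted p = 0.534 with an estimated correlation). Immediate early genes, which respond to growth factors and to tissue dissociation, were higher in 9 of 22, or 12 adjusted over the list alone, with Nr4a1 at 2.10 and Egr2 at 2.03 (camera adjusted p = 0.0026, adjusted p = 0.534 with an estimated correlation). Interferon response genes were higher in 3 of 8, or 4 adjusted over the list alone, namely Rtp4 (1.95), Mx1 (1.81) and Irf1 (1.77) (camera adjusted p = 0.0347, adjusted p = 0.715 with an estimated correlation). The calls for Mx1 and the immediate early gene Junb (1.66) ended under quantile normalization.

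In all, 1541 of 7796 genes differed, 952 higher and 589 lower in hair germ, with 2597 at an unadjusted p below 0.05 against 390 expected. Of these, 1536 had the same sign on all 3 days, and 924 also differed between dermal papilla and epithelium. The split depended on scaling: it was 693 and 794 under quantile normalization and 735 and 769 with median centring, where the median of all genes moved from 0.105 to -0.046 and -0.019. Camera called 10 of 34 lists with the preset correlation and 0 with an estimated one, and fry called 16. Without bulge replicates 1, 2 or 3 the count was 783, 973 or 863. Without the day 43 dermal papilla and day 69 hair germ arrays 1174 genes differed, 713 higher and 461 lower, and 1027 of them were among the 1541. There, mitosis genes were higher in 27 of 27, bulge markers lower in 12, DNA replication genes higher in 9, BMP antagonists lower in 4 and immediate early genes higher in 6. Leaving out every array with a GAPDH 3'/5' ratio above 6 keeps 1 hair germ array, so this contrast has no replicated check against 3' bias.

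The third comparison addressed what changed with age in all 3 populations. No gene passed (limma, 0 of 7796), with 565 genes at an unadjusted p below 0.05 for day 69 against day 43 and 398 for day 56 against day 43, where 390 are expected. Genes with the smallest p for day 69 were the fatty acid carrier gene Fabp4 at 2.01 ± 0.33 (SE, adjusted p = 0.631), the metallothionein gene Mt1 at 1.29, the EGF receptor inhibitor gene Errfi1 at 1.59, Hps4 at -1.26 and the ubiquitin ligase gene Fbxo32 at 1.04. All 5 had the same sign in the 3 populations. For day 56 these were Tcim at -1.14, the clock output gene Dbp at 1.32, the clock repressor gene Nr1d2 at 1.04, and the ribosomal protein genes Fau at 1.15 and Rps19 at 0.86, with adjusted p = 0.845. The median of all genes at day 69 moved from 0.069 to -0.024 under quantile normalization and -0.033 with median centring.

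Lists for day 69 were called by camera in 7 of 34 cases, 0 with an estimated correlation. Circadian clock genes had a median difference of 0.47, with 0 of 14 past the threshold over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000383, adjusted p = 0.323 with an estimated correlation). This was the only list that fry called. Immediate early genes had a median of 0.42 (camera adjusted p = 0.000418, adjusted p = 0.562 with an estimated correlation), WNT antagonists 0.62 (camera adjusted p = 0.00266, adjusted p = 0.34 with an estimated correlation), and FGF receptors and MAPK response genes 0.33 (camera adjusted p = 0.032, adjusted p = 0.562 with an estimated correlation). Mitosis genes had a median of -0.17 (camera adjusted p = 0.000599, adjusted p = 0.799 with an estimated correlation), DNA replication genes -0.19 (camera adjusted p = 0.013, adjusted p = 0.799 with an estimated correlation) and ribosome biogenesis genes -0.15 (camera adjusted p = 0.032, adjusted p = 0.833 with an estimated correlation). Of these 6 lists, 1 member was past the threshold adjusted over the list alone, in the FGF receptor list. For day 56 camera called 4 lists and fry 0. Mitosis genes had a median of -0.49 (camera adjusted p = 5.19e-10, adjusted p = 0.804 with an estimated correlation) and interferon response genes -1.19 (camera adjusted p = 0.000275, adjusted p = 0.804 with an estimated correlation). Cholesterol synthesis genes had -0.24 (camera adjusted p = 0.00611, adjusted p = 0.831 with an estimated correlation) and melanocyte genes 0.61 (camera adjusted p = 0.0178, adjusted p = 0.804 with an estimated correlation).

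Within dermal papilla, the question was which signals differ between late and early telogen. With 1 array per age, the values for each population below have no replicate check and no p. As lists, WNT ligands and R-spondins (median 0.46, percentile 93.9) and hedgehog pathway genes (0.39, 95.4) stayed inside the range of matched random lists between days 43 and 69, although single members differed at least 2-fold. The hedgehog list lay above the range with the mean of probe sets (0.515), and from day 56 to day 69 both lists did, at 0.62 (percentile 99.72) and 0.41 (percentile 98.73). The WNT and BMP modulator gene Sostdc1 stood at 8.05, 9.41 and 11.37 on days 43, 56 and 69, a difference of 3.32. Fgf7 was at 7.97, 9.23 and 9.89, and Fgf10 and Fgf13 were higher at day 69 by 1.15 and 1.08. Wnt5a was higher by 2.17, Rspo1 by 1.69, Rspo2 by 1.61, Sfrp2 by 1.77 and Sfrp1 by 1.43. The hedgehog receptor gene Ptch1, itself a hedgehog target, was higher by 2.11, Gli1 by 1.73 and Hhip by 1.52. Wnt5a and Ptch1 were not higher at day 56, with differences of -0.012 and -0.509 from day 43. Edn3, a melanocyte growth factor gene, was higher by 2.41, Mdk by 2.08, Bmp6 by 1.92, Fst by 1.79 and Bambi by 1.47. Signal genes at -1 or below were Fgf18 (-3.60), the activin subunit gene Inhbb (-1.90), Bmp8a (-1.28) and Tgfb2 (-1.12). Fgf18 was at 9.14, 5.11 and 5.55 on days 43, 56 and 69, and its mean in bulge was 10.87. The source of its signal on the day 43 dermal papilla array was not tested.

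The largest differences in dermal papilla were in the collagen gene Col14a1 (4.56), Pvalb (4.32), the IGF binding protein gene Igfbp5 (4.18), Laptm5 (3.93), Cd24a (3.88), Cyp2g1 (3.57), the proteoglycan gene Sdc3 (3.54) and the potassium channel gene Kcnj8 (3.40). In the other direction were Krt15 (-4.07), Padi4 (-3.85), Stc1 (-3.56), the epithelial regulator Trp63 (-3.39), Dsc2 (-2.64), Anxa8 (-2.50) and Orm1 (-2.43), beside Fgf18. Dermal papilla markers had a median difference of 1.40, at percentile 100 of matched random lists, and 10 of 17 were at least 2-fold higher, including Sox18 (2.75), Prom1 (1.79) and Corin (1.67). At day 56 their median was -0.02. All 4 keratinocyte markers measured were at least 2-fold lower, with a median of -1.49 at percentile 0, and of -1.65 at day 56. These 4 were measured because 1 of the 2 arrays was above its median. Without that filter 13 were measured and the median was -0.217, inside the random range. BMP antagonists had a median of 0.85 (percentile 99.97), Notch pathway genes 0.65 (99.5) with Hey2 at 2.19 and Hey1 at 1.55, growth factors of the remaining families 0.55 (99.7) and BMP response genes 0.68 (99.3). Immediate early genes had a median of 0.82 (percentile 100), with Nr4a1 and Atf3 at 2.75 each and Junb at 2.17. The 3 adipocyte markers measured were all at least 2-fold higher, Lpl by 2.84, Fabp4 by 2.09 and Cdo1 by 1.72. FGF ligands (median 0.84, percentile 98.9) fell inside the random range with a pseudocount of 64 or no filter, and WNT antagonists (0.51, 98.9) with no filter. These shifts sat beside the 3'/5' ratios, which were highest on day 43 in this population.

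In all, 761 of 7302 genes were at least 2-fold apart in dermal papilla, 543 higher and 218 lower at day 69. The split was 412 and 301 under quantile normalization and 366 and 346 with median centring, where the median of all genes moved from 0.066 to -0.034 and -0.1. From day 43 to day 56 the count was 637, 410 higher and 227 lower, and from day 56 to day 69 it was 377, 252 higher and 125 lower. A pseudocount of 64 gave 334.

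**Figure D2:**
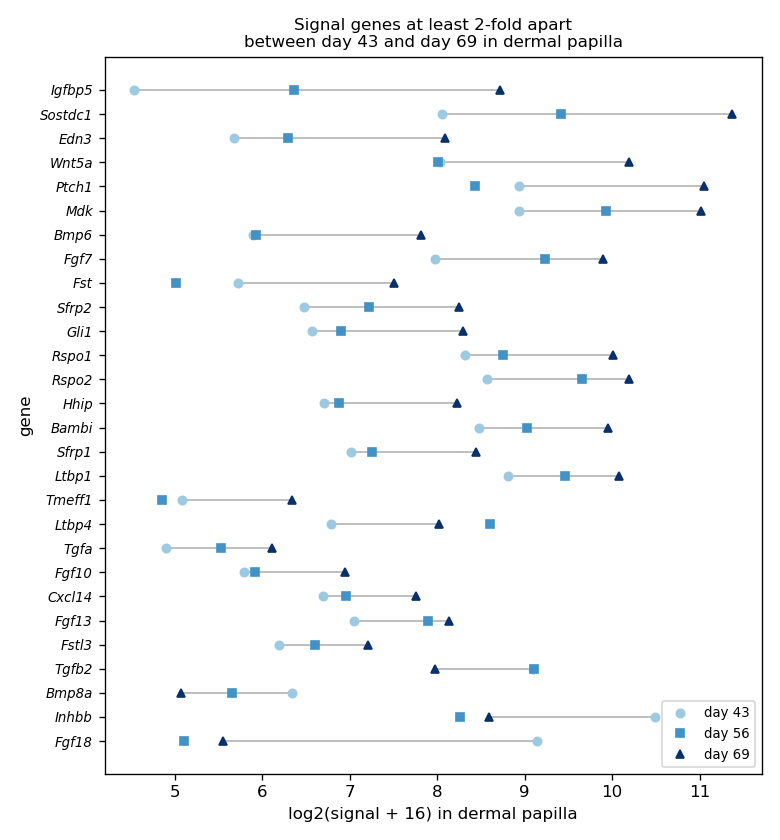
Levels of 28 signal genes at least 2-fold apart between the day 43 and day 69 dermal papilla arrays, as log2(signal + 16), with 1 symbol per day and a line joining days 43 and 69. Sostdc1, Rspo2, Mdk and Fgf7 lay between the other days at day 56, whereas Wnt5a and Ptch1 were at 8.01 and 8.43 on day 56 and at 10.19 and 11.05 on day 69.

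Within hair germ, lists of mitosis, DNA replication, ribosome biogenesis and interferon response genes were lower at day 69 than at day 43. Mitosis genes had a median of -0.84 (percentile 0), with 7 of 29 at least 2-fold lower, including Cenpf (-2.68), Ccnb2 (-2.10) and Cenpa (-1.72). At day 56 the median was -0.98 and 13 were at least 2-fold lower. Inner bulge and companion layer genes were lower on the same array, with a median of -2.56 at day 56 (percentile 0.01). They had 0.09 at day 69, but -0.505 with no filter, below the random range. DNA replication genes had a median of -0.91 (percentile 0), with 11 of 24 at least 2-fold lower, among them Fen1 (-1.41) and Gmnn (-1.39). Ribosome biogenesis genes had -0.73 (percentile 0) at day 69 but 0.006 at day 56, inside the random range, so their fall sat on the day 69 array alone. Interferon response genes were high at day 43: Rsad2, an antiviral gene, stood at 9.79, 4.98 and 7.74 on days 43, 56 and 69, Ifit1 at 8.01, 4.47 and 5.47, and the chemokine gene Cxcl10 at 8.89, 5.07 and 6.61. Their median was -0.96 at day 69 (percentile 0.01) and -3.28 at day 56 (percentile 0). Tslp, an epithelial cytokine gene, was lower by a log2 of -3.31, beside Synpo (-2.82), St6gal1 (-2.65), Irgm2 (-2.64), Mcm10 (-2.53) and Nkain1 (-2.51).

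Higher at day 69 in hair germ were Pdk4 (4.27) and Angptl4 (3.38), regulators of fuel use that respond to fasting, Krt77 (3.51), Map3k12 (3.08), Tesc (2.89), Spag1 (2.86), Fabp4 (2.85) and Fermt3 (2.84). Epidermal differentiation genes had a median of 1.00 (percentile 99.8), with Krtdap at 2.44 and Ly6d at 1.84, and 5 of 9 at least 2-fold higher. Under quantile normalization that median was 0.33, inside the random range. Leukocyte markers had a median of 1.19 (percentile 99.3), with 4 of 7 at least 2-fold higher, and fell inside the random range with no filter. Clock genes had a median of 0.58 (percentile 98.4), with Per1 at 1.88, Npas2 at 1.66 and Nr1d2 at 1.42, and fell inside the random range under quantile normalization at 0.415. FGF receptors and MAPK response genes had 0.70 (percentile 98.9), with Spry2 at 2.08 and Fgfr1 at 2.01, and fell inside the random range with no filter (0.567) or with the mean of probe sets (0.499). Immediate early genes had 0.67 (percentile 99.6). The quiescence gene Cdkn1b was higher by 2.53 and the WNT antagonist gene Dkk2 by 2.41. The 2 arrays had the highest 3'/5' ratios of the series, and the day 69 array the highest hybridization and poly-A control signals.

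In all, 1154 of 7447 genes were at least 2-fold apart in hair germ, 745 higher and 409 lower at day 69. The split was 509 and 610 under quantile normalization and 601 and 543 with median centring, where the median of all genes moved from 0.138 to 0.011 and 0.036. From day 43 to day 56 the count was 738, 458 higher and 280 lower. A pseudocount of 64 gave 468, no filter 1848 and the stricter filter 585.

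Within bulge, the fewest genes differed with age. Higher at day 69 were the acute phase gene Serpina3n (3.75), the glutamine synthetase gene Glul (3.49), Errfi1 (2.54), Tsc22d3 (2.45), which encodes a glucocorticoid-induced leucine zipper protein, Angptl4 (2.38), the protease gene Ctsl (2.26), Lbp (2.23) and the immune regulator Cd200 (2.22). Lower were the antioxidant gene Gpx2 (-2.19), Dclk1 (-2.17), Nrip3 (-2.12), Hps4 (-2.00), Stfa3 (-1.99), the water channel gene Aqp5 (-1.98), Crabp2 (-1.90) and Pdap1 (-1.89). Glul, Angptl4 and Ctsl were at -0.069, -1.99 and -0.074 when day 56 was compared with day 43. Clock genes had a median of 0.49 (percentile 99.99), with 0 of 12 at 2-fold and Tef at 0.86. FGF receptors and MAPK response genes had 0.59 (percentile 100), with Spred2 at 1.35 and Spry1 at 1.04, and WNT antagonists 0.76 (percentile 99.97), with Dkk3 at 1.34 and Wif1 at 1.21. Basement membrane and integrin genes had 0.32 (percentile 99.9). Dermal fibroblast markers, of a cell type outside the gate, had 0.52 (percentile 99.9), with Dcn at 1.84, and -0.74 at day 56. Epidermal differentiation genes had -0.46 (percentile 0.065) and cholesterol synthesis genes -0.27 (percentile 0.29). In all, 219 of 7183 genes were at least 2-fold apart, 124 higher and 95 lower, against 50 from day 43 to day 56 and 290 from day 56 to day 69. A pseudocount of 64 gave 88 and the stricter filter 114.

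Changes from day 43 to day 69 were compared between hair germ and bulge, the epithelial populations. Across 6766 genes r of the changes was 0.124, and 29 genes were at least 2-fold higher in both against 8.15 expected from the separate counts. Across 6437 genes of dermal papilla and bulge r was 0.138, with 19 against 4.64 expected. For dermal papilla and hair germ r was -0.129 across 6458 genes, with 23 against 27.5 expected. Subtracting the change in bulge from that in hair germ, 11 of 29 lists lay outside the random range. Inner bulge and companion layer genes had a median of -1.46 (percentile 0.01), epidermal differentiation genes 1.22 (percentile 99.95), DNA replication genes -0.64 (percentile 0), mitosis genes -0.70 (percentile 0.25) and interferon response genes -1.06 (percentile 0.22). Immediate early genes had 0.66 (percentile 98.9), ribosome biogenesis genes -0.40 (percentile 0.58) and oxidative phosphorylation genes -0.12 (percentile 0.6). Nearer the edge were WNT ligands and R-spondins at -0.76 (percentile 2.36), WNT antagonists at -0.67 (percentile 2.42) and BMP antagonists at -0.48 (percentile 2.22).

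**Figure D3:**
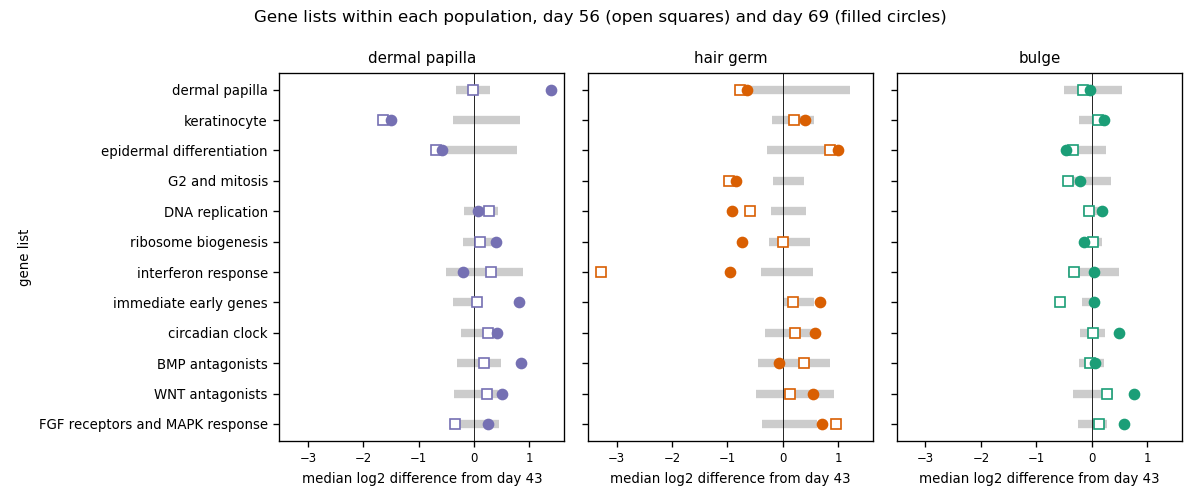
Median log2 difference of 12 gene lists from day 43 in each population, with day 56 as open squares and day 69 as filled circles. Grey bars span the central 95% of matched random lists at day 69, and a list with fewer than 3 members measured has no symbol; dermal papilla markers in dermal papilla were at -0.02 on day 56 and 1.40 on day 69, and interferon response genes in hair germ at -3.28 and -0.96.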

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

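The tests of dilution, of 3' bias, of time of day and of the hair germ mitosis genes were chosen only after the results were seen. Those of sample splits, of carried-over keratinocyte RNA and of held-out glucocorticoid targets were written down before they were run.

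In 3 cases a list lay above the range of matched random lists in 1 population and below it in another between days 43 and 69, and none of these differences was tested. Keratinocyte genes had a median of 0.22 in bulge and -1.49 in dermal papilla, a gap of 1.71. Epidermal differentiation genes had 1.00 in hair germ and -0.46 in bulge, a gap of 1.46. Ribosome biogenesis genes had 0.39 in dermal papilla and -0.73 in hair germ, a gap of 1.12. Under quantile normalization the higher median of each pair fell inside the random range, at 0.174, 0.33 and 0.232, and so did ribosome biogenesis genes in dermal papilla with the mean of probe sets (0.389) and keratinocyte genes there with no filter (-0.217). Hybridization control probe sets, which lie outside the genes measured, were 3.64 times as bright on the day 69 hair germ array as the median of the other 8 arrays, a difference that was not tested.

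Whether chance could give the gene counts was examined by splitting the arrays in every other way, with age left out for the populations and population kept as a block for the ages. For dermal papilla, 1 of 84 splits of 3 against 6 arrays gave as many genes, which was the real one, with 2329 against 616 for the highest other, which set hair germ against the rest. The real split ranked first, but every other split mixes sorted populations, which widens the spread within its groups. The ranking alone therefore does not exclude chance. For hair germ and bulge 1 of 10 splits reached the real count of 1437 and the highest other gave 0, and 10 splits are too few for a share under 0.05. For day 69 against day 43 the real count was 0 and the highest other 0, and for day 56 against day 43 they were 0 and 8. All 10 of 10 splits reach a count of 0 by construction, so these splits decide nothing, and 10 are too few in any case.

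In dermal papilla, dermal papilla genes were higher at day 69 than at day 43, when the 3'/5' ratios were highest, and the 4 keratinocyte markers that passed the filter were lower, although over all 13 the median was -0.217, inside the random range. With keratinocyte RNA carried into the day 43 sort, at least 45 of the 50 most abundant epithelial genes should be higher at day 43. Without it, at most 25 should be. The count was 30, between these bounds, so carried-over RNA cannot be told apart from a change within the sorted cells. Krt14 went from a signal of 5.26 to 39, but its promoter drives the reporter that the gate excludes, so it decides nothing. Dilution by keratinocyte RNA, at the median share of the 50 genes, would account for 2.13% of the median rise of the dermal papilla list. At the quartiles of that share over the genes it would account for 0.947% and 4.59%. That argues against dilution as the whole cause. The 50 genes were chosen as lower in dermal papilla on these same arrays, which holds the share down. The median rise of the dermal papilla list after day 56 was 69.6% of that from day 43 (bootstrap interval over genes 39.7 to 184). Medians do not add, so this is not a share of the rise. At day 56, when the GAPDH ratio had already fallen, the list's median difference from day 43 was -0.02. This argues against 3' bias as the whole cause, although the interval reaches below 50%. The stage of telogen may account for these values and stays open, as it was not tested with 1 array per age. Dermal fibroblast markers in dermal papilla had a median difference of -0.638 from day 43 to day 56, below the random range. From day 43 to day 69 they were inside it. Whether the mix of cells in the red gate changed was not tested.

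At day 69 the glucocorticoid target Tsc22d3 was among the largest differences in bulge, beside Glul, Angptl4 and Errfi1. In 18 further known targets the median difference was at percentile 100 in bulge (14 measured, median 0.753) and at percentile 100 in hair germ (13 measured, 0.956), which is consistent with glucocorticoid signalling in both, against percentile 91.3 (0.222) in dermal papilla. Another time of day at collection should raise clock genes of the Dbp phase and lower those of the Arntl phase. In bulge the Arntl phase rose as well, with a median of 0.369 (percentile 97.1). The Dbp phase exceeded it by 0.207, with an interval over genes of -0.048 to 0.552. That interval ended below the gap set in favour of this cause but passed the bound set against it. By that gap alone a smaller shift in time cannot be told apart from glucocorticoid signalling in bulge. The bulge targets had -0.08 (percentile 8.52) from day 43 to day 56 and 0.773 (percentile 100) from day 56 to day 69. Clock genes of the Dbp phase had 0.456 (percentile 99.9) and then 0.149 (percentile 75.1). Targets and clock genes thus rose in different intervals. This argues against a shift in time as the whole cause in bulge, with 1 array per day. In hair germ the medians of the Dbp and Arntl phases were 0.896 and 0.345, and their difference was not tested. The hair germ targets were already at 0.452 (percentile 99.5) from day 43 to day 56. Their day 69 value rests on 2 arrays with high 3'/5' ratios, 1 of them with outlying control signals. Stress, fasting and the stage of telogen stay open as sources and were not tested.

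In hair germ, mitosis genes were highest on the day 43 array. The day 69 array with its outlying control signals is argued against as the whole cause, because the median was already -0.979 at day 56 (random range -0.151 to 0.31). The 3' bias of day 43 is argued against as the whole cause, because the median was -0.839 (random range -0.184 to 0.384) at day 69, when the ratios were near those of day 43. Each argument rests on the array open to the other cause. Both causes together, with 3' bias behind the day 56 fall and the outlying array behind the day 69 fall, therefore stay open. More differentiated epidermal cells in the day 43 gate are argued against, because epidermal differentiation genes were higher at day 56 by 0.855 (random range -0.458 to 0.276). Inner bulge cells in the gate, whose genes had -2.56 at day 56, stay open for the day 56 fall. At day 69 their genes had 0.09, which leaves the day 69 fall unaccounted for. With no filter they had -0.505 at day 69, below the random range, so this is not settled. A change of cycling with the stage of telogen may account for both falls and stays open. Neither explanation was tested.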

How the results depend on the processing

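Leaving out the day 43 dermal papilla and day 69 hair germ arrays, leaving out the 3 arrays with high 3'/5' ratios, and comparing day 69 with day 56 were chosen only after the results were seen. Signals near background limit every fold, because the pseudocount shrinks the differences of dim genes, and 1 array per population and age leaves the comparisons within a population with no estimate of error. Using only the arrays compared leaves out no array for dermal papilla against epithelium, so it gave no value there. With an estimated correlation all 33 list calls of the 4 contrasts were lost.

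For dermal papilla against epithelium the count was 3145, and 1980 with a 2-fold minimum; leaving out 1 array gave 2456 to 3205. For hair germ against bulge it was 1541, 1062 with a 2-fold minimum, 783 to 1609 with 1 array left out, 783, 973 and 863 without bulge replicates 1, 2 and 3, and 1000 without both the 3 arrays with high 3'/5' ratios and the age term. That last fit holds 1 hair germ array, takes its spread from the other populations and cannot separate the 2 choices. Both age contrasts gave 0 in every setting run for them, which left out the fits with no age term and those without 2 or 3 arrays. Within dermal papilla the 761 became 334 with a pseudocount of 64, 405 with the stricter filter and 377 for day 69 against day 56. Within hair germ the 1154 became 468 with a pseudocount of 64, 585 with the stricter filter, 1848 with no filter and 738 at day 56. Within bulge the 219 became 88, 114 and 50 with a pseudocount of 64, the stricter filter and day 56. The cause of these shifts was not tested, except that a larger pseudocount shrinks folds by construction.

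These turned direction. With the mean of probe sets Cdkn1a in dermal papilla against epithelium went to 0.177. Fry gave the basement membrane and integrin list the opposite direction there (adjusted p = 0.0123). With no filter Mbp in dermal papilla went to -0.885 and Igfbp5 in hair germ to -0.713, and with a pseudocount of 1 Sox9 in hair germ went to 0.227. With day 56 in place of day 69, dermal papilla gave Anxa8 0.11, Thy1 0.172, Id2 -0.29, Wnt5a -0.012, Ptch1 -0.509, Hey2 -0.588, Nid1 -0.164 and Tgfb2 0.01. Hair germ gave St6gal1 0.898, Perp -0.236, Elovl4 -0.356, Dut 0.012, Rrp9 0.079 and Pmvk -0.179. Bulge gave Glul -0.069, Angptl4 -1.988, Ctsl -0.074, Stfa3 0.208, Pdap1 0.367, Dcn -1.393, Fen1 0.028, Gdf10 0.057, Ptch1 -0.016, Igfbp3 0.149, Maff -0.659, Ccn1 -0.491 and the dermal fibroblast list -0.741. Counting each named gene of the tested contrasts once per array left out, whether or not it had passed, the outcome was the same in 3482 cases, weaker in 187 and stronger in 3.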

Other observations

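Several lists were higher in hair germ at day 56 than at day 43. Hedgehog pathway genes had a median difference of 0.79 (percentile 99.9), but -0.16 between days 56 and 69 (percentile 16.1), with Gli1, a direct hedgehog target, at 5.48, 7.64 and 6.32 on days 43, 56 and 69. BMP response genes had 0.47 (percentile 99.7), with Id1 at 7.27, 9.50 and 7.64. Hair matrix and lineage genes had 0.73 (percentile 99.8), with Runx1 higher by 1.48, Msx2 by 1.29 and Hoxc13 by 1.16. The stem cell receptor gene Lgr5 stood at 7.58, 9.65 and 8.10. Dermal fibroblast genes, of cells outside the gate, had 1.29 (percentile 99.98), with Col1a2 at 2.19 and Col3a1 at 1.74. This array had the lowest 3'/5' ratios of the hair germ arrays.

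Inner bulge keratins, like antiviral genes, were lowest in hair germ at day 56. The inner bulge and companion layer list had a median of -2.56 at day 56 (percentile 0.01), with Krt6a at 12.18, 8.09 and 10.37 and Krt6b at 11.41, 5.67 and 12.17 on days 43, 56 and 69. In dermal papilla, cholesterol synthesis genes had a median of -0.80 at day 56 (percentile 0), with Hmgcs1 at -2.07, and -0.03 at day 69. In bulge, immediate early genes had -0.57 at day 56 (percentile 0), with Egr2 at -1.74 and Nr4a1 at -1.66, and 0.04 at day 69.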
